A study of Homo sapiens with 14 samples.

How the data were processed

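The samples were 14 RNA sequencing libraries from xenografts of UMUC3, a human bladder cancer cell line, grown in mice. The cells were control cells, titled as carrying a control short hairpin RNA, or FASN knockdown cells, whose knockdown method the labels do not state. Before engraftment they were kept in regular medium or pre-exposed to 10% cigarette smoke medium (CSM), whose preparation and exposure time the labels do not give. The groups were control (n = 3), FASN knockdown (n = 3), control after CSM (n = 4) and FASN knockdown after CSM (n = 4), and every library took its group and replicate number from its label. Per the labels' protocols, total RNA was taken from frozen xenograft tissue with a column kit. FastQC, cutadapt and Salmon and the build GRCh38 are named in the submitters' processing notes. Their versions, the Salmon settings and the annotation release are not given in the sources used here.

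The authors deposited a Salmon table per library, with expected counts (estimated reads per transcript, not normalised) and TPM for 252048 human transcripts, and per the file headers also the length and effective length of each transcript. Mouse transcripts are not part of these tables, so reads of the mouse host were either left unassigned or given to human transcripts similar in sequence. The expected counts were summed over the transcripts of each of 62749 genes and rounded to whole numbers, because the count models need them. The summed counts per library ranged from 15810287 to 45209466. A share of the counts, 2.64% to 25.6% per library, fell on RN7SL1 and RN7SL2, the 7SL RNA of the signal recognition particle.

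Genes were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM normalisation and filterByExpr at its defaults (a minimum count of 10 and a minimum total of 15), which kept 22560 genes, 14519 of them protein coding. All 14 libraries entered one fit with a coefficient per group, so that the groups shared 10 residual degrees of freedom. The biological coefficient of variation was 0.444. A gene was called at a Benjamini-Hochberg adjusted p below 0.05, with no minimum fold change, and every adjusted p of a gene in the text is from this test unless another is named. The contrasts were knockdown against control in each medium, CSM against regular medium in each kind of cell, and the interaction, which is the knockdown effect after CSM minus that in regular medium. Levels are edgeR's CPM on TMM-scaled totals. The labels do not say that the libraries of a group came from separate animals, so the p-values measure the spread between these libraries, which may in part be technical. Differences of FASN between groups were also tested with an exact, two-sided permutation test.

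Before the data were examined, 25 gene lists, the rule for named genes, the tests and the first set of alternatives were fixed. The lists were de novo fatty acid synthesis, cholesterol synthesis and SREBP2 targets, fatty acid oxidation, fatty acid uptake and lipid storage, phospholipid and sphingolipid synthesis, aryl hydrocarbon receptor targets, NRF2 and oxidative stress, p53 targets and DNA damage, glycolysis, hypoxia response, nuclear oxidative phosphorylation, mitochondrially encoded genes, cell cycle and proliferation, mesenchymal genes and EMT, epithelial and urothelial genes, interferon response, inflammatory and NF-kB targets, unfolded protein and integrated stress response, ribosomal protein genes, immediate early and tissue handling genes, and markers of host fibroblasts and matrix, endothelium, myeloid cells and leukocytes, adipocytes and skeletal muscle. Lists with at least 5 tested members were tested with camera from limma 3.58.1 at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 24 lists of a contrast, and again with camera at a correlation estimated from the data and with fry. The skeletal muscle list had only 3 tested members and was not tested. Named genes were FASN, then per contrast the 8 protein-coding genes with the largest rise and the 8 with the largest fall among those called, at a mean of at least 2 CPM and without overlap between the groups, then up to 3 called members of each list, or the 2 members with the smallest p where none was called.

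The alternatives were DESeq2 1.42.0 in place of edgeR, relative log expression or upper-quartile factors, no filter on low counts, a filter of 2 CPM in 3 libraries, protein-coding genes alone, only the groups of a contrast in the fit, the replicate number as a block, a length offset from the effective lengths, limma with trend on log2(TPM + 1), a host marker score as covariate, a minimum absolute log2 fold change of 1, and each library left out in turn. After the data had been seen, the log2 share of 7SL was tried as a covariate, and the fit was repeated without the 2 libraries with over 15% 7SL. Correlations across libraries used 100000 permutations in scipy 1.17.1.

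The tests were also run on simulated data, with counts drawn from the real means, dispersions and totals of the 22560 genes. At each fold size 100 genes were changed, all taken from the 14098 at a mean of 2 CPM or more. Recovery of genes below that level was not measured. Of genes changed 4-fold, 67% were recovered for knockdown in regular medium, 75% for knockdown after CSM, 72% for CSM in control cells, 72% for CSM in knockdown cells and 28% for the interaction, and of genes changed 2-fold 9%, 11%, 14%, 15% and 0%. Data simulated without any change gave 0 called genes and 0 called lists in each contrast, with 4.54% to 4.81% of genes at an unadjusted p below 0.05. Genes were drawn independently of each other there, so the 0 called lists do not test the preset correlation between genes. Small changes of single genes were therefore often missed at this depth and spread. Positions of genes are on GRCh38 from GENCODE release 29, matched by gene identifier, which covered 20874 of the 22560 tested genes (92.5%). The SPANX genes are near-identical copies, and the division of their reads among them is uncertain.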

Results

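RNA was sequenced in 14 libraries from xenografts of UMUC3, a human bladder cancer line, to compare tumours of control cells and of FASN knockdown cells, each grown from cells kept in regular medium or pre-exposed to cigarette smoke medium (CSM). FASN encodes fatty acid synthase, the enzyme that makes palmitate. There were 3 control and 3 FASN knockdown libraries from regular medium, and 4 of each after CSM. The summed counts ran from 15810287 in replicate 2 of the FASN knockdown to 45209466 in replicate 3 of the control after CSM, and 22560 genes were tested. Among the host marker lists the median level was 2.35 CPM for fibroblast and matrix genes and 0.291 CPM for endothelial genes. It was 0.0736 CPM for myeloid and leukocyte genes, 0.0949 CPM for adipocyte genes and 0.0353 CPM for skeletal muscle genes. Single members stood higher, such as CD68 at 74.3 CPM and ADIPOR2 at 142 CPM. As mouse transcripts were not quantified, these levels do not show how many mouse cells the samples held. The 7SL RNA took 8.13% ± 1.58 (SD, n = 3) of the counts in the control libraries, 14.1% ± 10.9 (SD, n = 3) in the FASN knockdown, 7.94% ± 5.63 (SD, n = 4) in the control after CSM and 4.83% ± 4.29 (SD, n = 4) in the libraries labelled FASN knockdown after CSM.

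FASN RNA was low in all 3 knockdown libraries from regular medium, and its level varied among the 4 libraries labelled FASN knockdown after CSM. FASN (ENSG00000169710.9) lies on chromosome 17 from 82078333 to 82098332 (GRCh38, minus strand). In regular medium its mean level was 451 CPM ± 104 (SD, n = 3) in control libraries and 117 CPM ± 16.1 (SD, n = 3) in knockdown libraries, which is 26.0% of control. After CSM the control libraries held 431 CPM ± 48.9 (SD, n = 4) and the libraries labelled FASN knockdown after CSM held 291 CPM ± 137 (SD, n = 4), which is 67.6% of control. In these libraries FASN stood at 50.9%, 38.5%, 69.8% and 111% of the control mean in replicates 1 to 4. The level in replicate 4 goes against its label, and every direction drawn from this group below carries that limit. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, FASN fell by 1.94 on the log2 scale in regular medium (SE 0.33, adjusted p = 0.0245). The log2 fold change after CSM was -0.57 (SE 0.28, 95% interval -1.15 to 0.02) and did not pass the same edgeR test (adjusted p = 0.288). Its direction turned to 0.19 on the TPM scale (limma adjusted p = 0.802), where the median of all genes moved by 0.39. An exact permutation test of both directions gave p = 0.1 in regular medium, the smallest value that 3 against 3 libraries allow, and p = 0.114 after CSM. The call in regular medium was lost in each of the 6 fits that left out 1 library, with edgeR adjusted p from 0.0515 to 0.127, the highest without replicate 1 of the control. The log2 fold change stayed between -2.06 and -1.72.

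**Figure D1:**
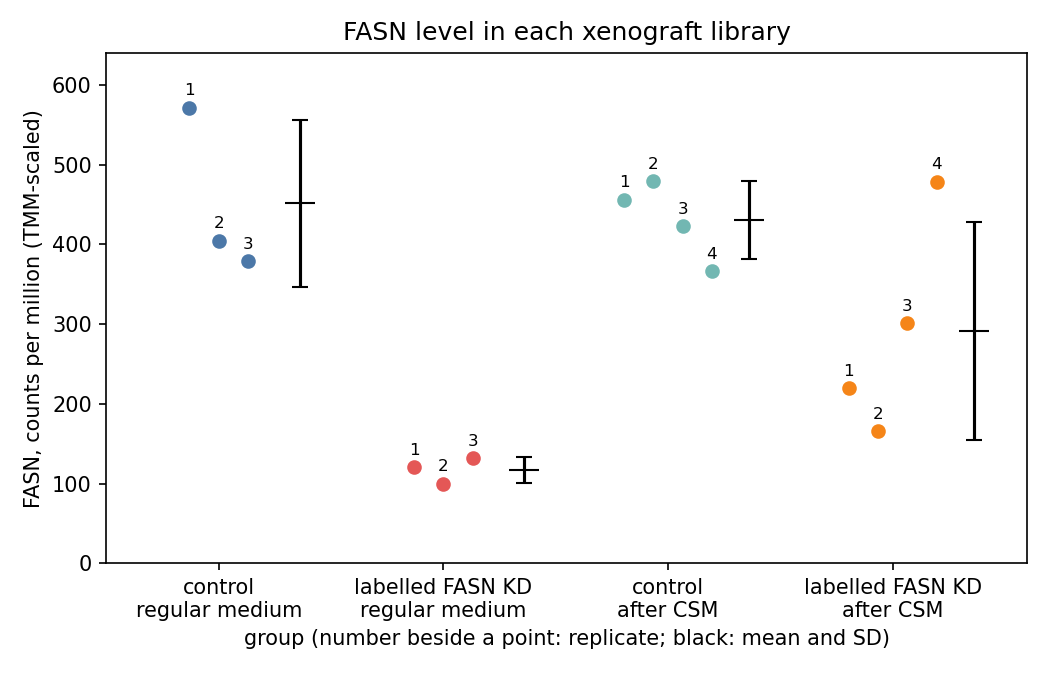
FASN level in CPM (linear axis from 0) for each library, numbered by replicate, with the group mean and SD in black. Knockdown libraries from regular medium lie at 99.9 to 132 CPM, below all control libraries. Replicate 4 of the libraries labelled FASN knockdown after CSM lies at 479 CPM, within the range of the controls.

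In regular medium a group of genes that control libraries expressed was nearly absent from the FASN knockdown libraries, which need not be an effect of the knockdown itself. AJAP1, LPAR1 and the SPANX copies were among them. AJAP1 (chromosome 1, 4654732 to 4792534), a membrane protein of adherens junctions, had a mean of 39.1 CPM ± 22.6 (SD, n = 3) in control libraries and 0.414 CPM ± 0.257 (SD, n = 3) in knockdown libraries. LPAR1 (chromosome 9, 110873263 to 111038458), a receptor for lysophosphatidic acid, had 20.2 CPM ± 6.63 and 0.250 CPM ± 0.362 (SD, n = 3 each). COL4A6 (chromosome X, 108155607 to 108439497), a basement membrane collagen chain, rose from 5.16 CPM ± 3.44 to 56.1 CPM ± 2.91 (SD, n = 3 each). Of 22560 genes, 46 were called, 6 higher and 40 lower, and 2049 had an unadjusted p below 0.05. On the TPM scale, where the median of all genes moved by -0.14, 17 genes were called, 0 higher and 17 lower.

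Among the largest falls, AJAP1 fell by 6.53 on the log2 scale (SE 0.60, adjusted p = 0.000255 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and LPAR1 fell by 6.22 (SE 0.77). The cation channel gene TRPC4 (chromosome 13, 37636636 to 37870425) fell by 6.75 (SE 0.86) and the transcription factor gene TCF21 fell by 6.17 (SE 0.88). GULP1, an adaptor for the uptake of dying cells, had 639 counts over the 3 control libraries and 2 counts over the 3 knockdown libraries. SPANXB1 and SPANXD, testis genes that many tumours express, fell by 6.79 and by 5.89, and SPANXA1 had 661 counts in control libraries and 0 in knockdown libraries, at least 138-fold lower against a floor of 3 counts over the group. Reads of the SPANX copies cannot be assigned with certainty, so these values are uncertain for each single copy. COL4A6 rose by 3.45 (SE 0.53, edgeR adjusted p = 0.0120). The neuronal genes PRUNE2 and CSMD2 rose by 2.17 and 1.89. PRICKLE1, of planar cell polarity signalling, rose by 1.93, and the protocadherin gene PCDHGB1 rose by 1.67. Of all tested genes, 11.8% separated the groups without overlap, where chance gives 10%. SPANXA1, GULP1, SPANXB1, TRPC4, AJAP1, LPAR1 and TCF21 kept their calls in each fit that left out 1 library. The other calls ended in at least 1 of these 6 fits. The highest edgeR adjusted p was 0.103 for COL4A6, 0.0734 for CSMD2 (lost also without control replicate 3), 0.102 for PRICKLE1 and 0.153 for PCDHGB1 (each without control replicate 2). It was 0.180 for PRUNE2 without control replicate 1, and 0.175 for SPANXD without knockdown replicate 2.

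Genes of cholesterol synthesis stood higher as a group in 2 of the 3 knockdown libraries. Their mean log2 CPM was 6.38 and 6.74 in knockdown replicates 1 and 2, which hold the most 7SL, and 5.18 in replicate 3, below the controls at 5.60, 5.46 and 5.48. All 24 tested members of the cholesterol synthesis and SREBP2 list had a positive log2 fold change, with a median of 0.88, and the list rose in camera with a preset correlation (adjusted p = 1.79e-08). With an estimated correlation the adjusted p = 0.742, and no member was called over all genes, with 2 called when adjusted over the list alone. Without knockdown replicate 2 the median was 0.52 (adjusted p = 0.00472). LSS, which closes the sterol ring, had a log2 fold change of 0.95 (SE 0.25, edgeR adjusted p = 0.186). The p53 list rose with a median of 0.53 and 20 of 21 members positive (adjusted p = 4.56e-05, and adjusted p = 0.742 with an estimated correlation), with FAS at 0.86 and DDB2 at 2.39. Replicate 3 carried most of this rise: the mean log2 CPM was 5.21 and 6.09 in knockdown replicates 2 and 3, while replicate 1 lay within the range of the controls (4.74 to 4.83), and without replicate 3 the median was 0.25 (adjusted p = 0.0329). The NRF2 list fell with a median of -0.21 and 24 of 29 members negative (adjusted p = 0.00742, and adjusted p = 0.742 with an estimated correlation), with the cystine transporter gene SLC7A11 at -1.99. Glycolysis genes fell with a median of -0.37 (adjusted p = 0.0110) and NF-kB targets fell with a median of -0.45 (adjusted p = 0.0254), both at adjusted p = 0.823 with an estimated correlation. Ribosomal protein genes fell by a median of 0.14 and interferon genes rose by a median of 0.18, each at adjusted p = 0.0420 and at adjusted p = 0.823 with an estimated correlation, with the interferon median at -0.10 on the TPM scale. The 7SL shares of the knockdown libraries in this comparison were 12.9%, 25.6% and 3.89%. In the host fibroblast and matrix list, which fell (median -0.18, adjusted p = 0.0172, and adjusted p = 0.742 with an estimated correlation), COL5A1, a fibrillar collagen that control libraries expressed at 45.5 CPM ± 8.87 (SD, n = 3), fell by 2.06 (SE 0.35, edgeR adjusted p = 0.0243). Adjusted over the list alone 1 gene was higher and 5 were lower. The call of COL5A1 was lost in 5 of 6 fits that left out 1 library, with an edgeR adjusted p of up to 0.114 without knockdown replicate 2. Of de novo fatty acid synthesis, FASN was the 1 called member of 20, over all genes and adjusted over the list alone, and the list was not called (median 0.16, adjusted p = 0.745).

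Several of these list calls in regular medium rested on single libraries. Without knockdown replicate 3 the NRF2 and glycolysis calls ended (adjusted p = 0.248 and 0.797), and both also ended without control replicate 1. The glycolysis call and the NF-kB call ended without control replicate 2 (adjusted p = 0.462 for NF-kB), and NF-kB also without control replicate 1 and knockdown replicate 3. The interferon call ended without control replicates 1 and 3 and knockdown replicates 1 and 2 (adjusted p of up to 0.985 without control replicate 3). The ribosomal call ended without control replicate 1 and knockdown replicates 1 and 3 (up to 0.784 without control replicate 1), and the host fibroblast call without knockdown replicate 1 (0.0961). Cholesterol synthesis and p53 targets kept their calls. Not called were fatty acid oxidation (median 0.05, mean -0.11, adjusted p = 0.672), fatty acid uptake and storage (median -0.05, mean 0.02, adjusted p = 0.841), phospholipid and sphingolipid synthesis (median 0.05, adjusted p = 0.318), aryl hydrocarbon receptor targets (median -0.35, adjusted p = 0.230) and oxidative phosphorylation (median -0.06, adjusted p = 0.630). Nor were mitochondrially encoded genes (median 0.39, adjusted p = 0.230), the cell cycle (median -0.07, adjusted p = 0.745), mesenchymal genes (median 0.13, adjusted p = 0.159), epithelial genes (median -0.40, adjusted p = 0.212), hypoxia genes (median -0.31, adjusted p = 0.159), immediate early genes (median -0.31, adjusted p = 0.0644) and stress response genes (median -0.15, adjusted p = 0.230). Endothelial (median 0.39, adjusted p = 0.672), myeloid (median 0.84, adjusted p = 0.282) and adipocyte (median -0.04, adjusted p = 0.832) markers were not called.

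After CSM, sterol synthesis genes were higher as a group and fatty acid oxidation genes lower in the libraries labelled FASN knockdown than in controls. Neither list was called with an estimated correlation. Mean log2 CPM of the cholesterol synthesis list was 6.15, 6.64, 6.88 and 7.13 in replicates 1 to 4 of these libraries. In controls after CSM it was 5.86, 5.56, 6.28 and 5.50. The groups overlap, and the highest value is in replicate 4, whose FASN level goes against its label. The fatty acid oxidation list lay at 4.13 to 4.25, below every control (4.75 to 4.87). LSS (chromosome 21, 46188141 to 46228824) rose from 82.6 CPM ± 13.4 to 196 CPM ± 49.8 and MVK, the mevalonate kinase gene, rose from 21.3 CPM ± 3.68 to 58.1 CPM ± 18.0 (SD, n = 4 each). CPT1A (chromosome 11, 68754620 to 68844410), which carries fatty acids into mitochondria, fell from 390 CPM ± 44.1 to 164 CPM ± 26.3 (SD, n = 4 each). The genes nearly absent in regular medium were nearly absent here too, with AJAP1 at 28.5 CPM ± 9.96 in control libraries and 0.388 CPM ± 0.191 in the libraries labelled FASN knockdown after CSM (SD, n = 4 each). There were 264 called genes, 97 higher and 167 lower (36.7% higher), and 4167 with an unadjusted p below 0.05. Replicate 4, whose FASN level goes against its label, is among these libraries, and without it 142 genes were called.

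Among the largest falls was that of SPANXA1, with 1568 counts in control libraries and 0 in the libraries labelled FASN knockdown after CSM (at least 541-fold lower against a floor of 3 counts over the group). SPANXD fell by 7.98 on the log2 scale and SPANXA2 fell by 6.96. TRPC4 fell by 7.53 (SE 0.79), TCF21 fell by 7.27 (SE 0.81) and AJAP1 fell by 6.19 (SE 0.50, adjusted p = 4.61e-05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). PPARGC1A, a coactivator of mitochondrial biogenesis, fell by 7.21 (SE 1.16, edgeR adjusted p = 0.00751) from a control level of 15.3 CPM ± 21.0 (SD, n = 4) that replicate 1 dominated at 46.4 CPM. MTUS1, a microtubule-associated tumour suppressor gene, fell by 6.32 (SE 0.92). Among the rises, ADAMTSL1 and ADAMTS14, of the extracellular matrix, rose by 4.00 (SE 0.71, edgeR adjusted p = 0.0144) and by 2.09 (SE 0.39, edgeR adjusted p = 0.0184). The calcium channel gene RYR2 rose by 2.76, TENM1 by 2.66, the integrin gene ITGAX by 1.92, the Wnt antagonist SFRP1 by 1.90, the myosin kinase gene MYLK by 1.89 and the protocadherin gene PCDHGA8 by 1.88. Of all tested genes, 16.2% separated the groups without overlap, where chance gives 2.86%. In the 8 fits that left out 1 library, RYR2, TENM1, ITGAX, SFRP1, MYLK and PCDHGA8 lost their calls in 5 to 7, with edgeR adjusted p of up to 0.115, 0.150, 0.105, 0.0954, 0.111 and 0.129. ADAMTSL1 lost its call without control replicate 4 (0.0528) and ADAMTS14 without knockdown replicate 1 (0.0539). The falls named here kept theirs.

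Of the cholesterol synthesis and SREBP2 list, 4 of 24 members rose and 12 did when adjusted over the list alone, and the list rose (median 0.89, adjusted p = 4.94e-11 in camera with a preset correlation). With an estimated correlation the adjusted p = 0.371, and fry gave an adjusted p = 0.0638. LSS rose by 1.24 (SE 0.22, edgeR adjusted p = 0.0128), MVK by 1.45 (SE 0.25, edgeR adjusted p = 0.0130) and HSD17B7 by 1.39 (SE 0.25, edgeR adjusted p = 0.0153). Among the 8 fits without 1 library, MVK lost its call without control replicate 4 (edgeR adjusted p = 0.0513) and HSD17B7 without control replicates 2 and 4 and knockdown replicate 3, with an adjusted p of up to 0.0607 without control replicate 2. Of the fatty acid oxidation list, 3 of 25 members fell and 7 did when adjusted over the list alone. The list fell (median -0.35, adjusted p = 8.06e-06, adjusted p = 0.0698 with an estimated correlation), and fry gave an adjusted p = 0.00124. CPT1A fell by 1.25 (SE 0.18, edgeR adjusted p = 0.00323), and the thiolase gene ACAA2 fell by 1.24 (SE 0.24, edgeR adjusted p = 0.0239) but lost its call in 6 of the 8 fits without 1 library, with an adjusted p of up to 0.0798 without knockdown replicate 1. De novo fatty acid synthesis had no called member, 5 that rose when adjusted over the list alone, and a median of 0.11 (adjusted p = 0.242), with ACSS2 at 1.11 (SE 0.26, edgeR adjusted p = 0.0501).

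Groups of growth and respiration genes stood lower in the libraries labelled FASN knockdown after CSM. The mean log2 CPM per library did not overlap with controls for ribosomal protein, oxidative phosphorylation, NRF2 and epithelial genes. It overlapped for mitochondrially encoded, glycolysis, cell cycle, hypoxia, immediate early and stress response genes. All 60 ribosomal protein genes were negative (median -0.80, adjusted p = 1.54e-19) and 46 of 48 nuclear genes of oxidative phosphorylation were negative (median -0.64, adjusted p = 5.29e-13), while all 13 mitochondrially encoded genes were positive (median 0.97, adjusted p = 0.000211). These lists fell, fell and rose in camera with a preset correlation, with adjusted p = 0.371, 0.371 and 0.406 with an estimated correlation, and 6, 12 and 0 members were called when adjusted over the list alone. Glycolysis genes fell, with all 23 negative (median -0.73, adjusted p = 2.36e-06), as did the NRF2 list (median -0.48, adjusted p = 1.55e-05, 3 members lower when adjusted over the list alone), both at adjusted p = 0.371 with an estimated correlation. Cell cycle genes fell (median -0.43, adjusted p = 1.32e-06, and adjusted p = 0.406 with an estimated correlation), with the cyclin genes CCNB2 at -0.75 and CCNA2 at -1.01. MKI67 of the same list went the other way, at 0.33 (SE 0.27). Hypoxia genes fell (median -0.61, adjusted p = 0.000592), immediate early genes fell (median -0.67, adjusted p = 0.00119) and genes of the unfolded protein and integrated stress response fell (median -0.37, adjusted p = 0.00391), with adjusted p = 0.520, 0.467 and 0.434 with an estimated correlation. The hypoxia call and the immediate early call ended without control replicate 1 (adjusted p = 0.0727 and 0.213). Epithelial and urothelial genes fell (median -0.26, adjusted p = 0.0139, adjusted p = 0.180 with an estimated correlation, fry adjusted p = 0.00503), with 1 of 19 called and 4 lower when adjusted over the list alone. That gene, the desmosome gene DSP, fell by 3.97 (SE 0.92, edgeR adjusted p = 0.0498) from 2.15 CPM ± 2.61 (SD, n = 4). Its call ended in 7 of 8 fits without 1 library, with an edgeR adjusted p of 0.152 without control replicate 4. Several members of this list were barely expressed, such as CDH1 at a mean of 0.540 CPM and GRHL2 at 0.195 CPM over all libraries. Others were well expressed, such as KRT18 at 146 CPM and TJP1 at 131 CPM.

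The 7SL share was 2.73%, 11.3%, 2.64% and 2.67% in the libraries labelled FASN knockdown after CSM, and 4.20% to 16.3% in the control libraries after CSM. On the TPM scale the median of all genes moved by 0.39 in this comparison, and 9 of these 10 falling lists had medians of 0.00 to 0.37 there, against -0.15 for ribosomal protein genes. Relative to that shift, all 12 called lists kept their direction on the TPM scale. On the TPM scale 59 genes were called, 35 higher and 24 lower (59.3% higher). With upper-quartile factors, which moved the median of all genes by 0.16, 282 genes were called, 166 higher and 116 lower (58.9% higher). No list had a call in camera with an estimated correlation in any of the 5 contrasts. In the host fibroblast and matrix list, THY1 fell by 1.64 (SE 0.36, edgeR adjusted p = 0.0409) and POSTN fell by 5.08 (SE 1.12, edgeR adjusted p = 0.0420), with 1 member higher and 3 lower when adjusted over the list alone, and the list was not called (median -0.09, adjusted p = 0.162). In the fits without 1 library, THY1 lost its call in 7 of 8 and POSTN in 6 of 8, with edgeR adjusted p of up to 0.117 without control replicate 3 and 0.120 without knockdown replicate 1. Endothelial (median -0.26, adjusted p = 0.383), myeloid (median 0.08, adjusted p = 0.574) and adipocyte (median -0.15, adjusted p = 0.673) markers were not called. Neither were fatty acid uptake (median -0.13, adjusted p = 0.394), phospholipid synthesis (median -0.06, adjusted p = 0.574), aryl hydrocarbon receptor targets (median -0.26, adjusted p = 0.107), p53 targets (median -0.06, adjusted p = 0.580), mesenchymal genes (median -0.20, adjusted p = 0.302), NF-kB targets (median -0.24, adjusted p = 0.242) and interferon genes (median -0.06, mean 0.09, adjusted p = 0.620).

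**Figure D2:**
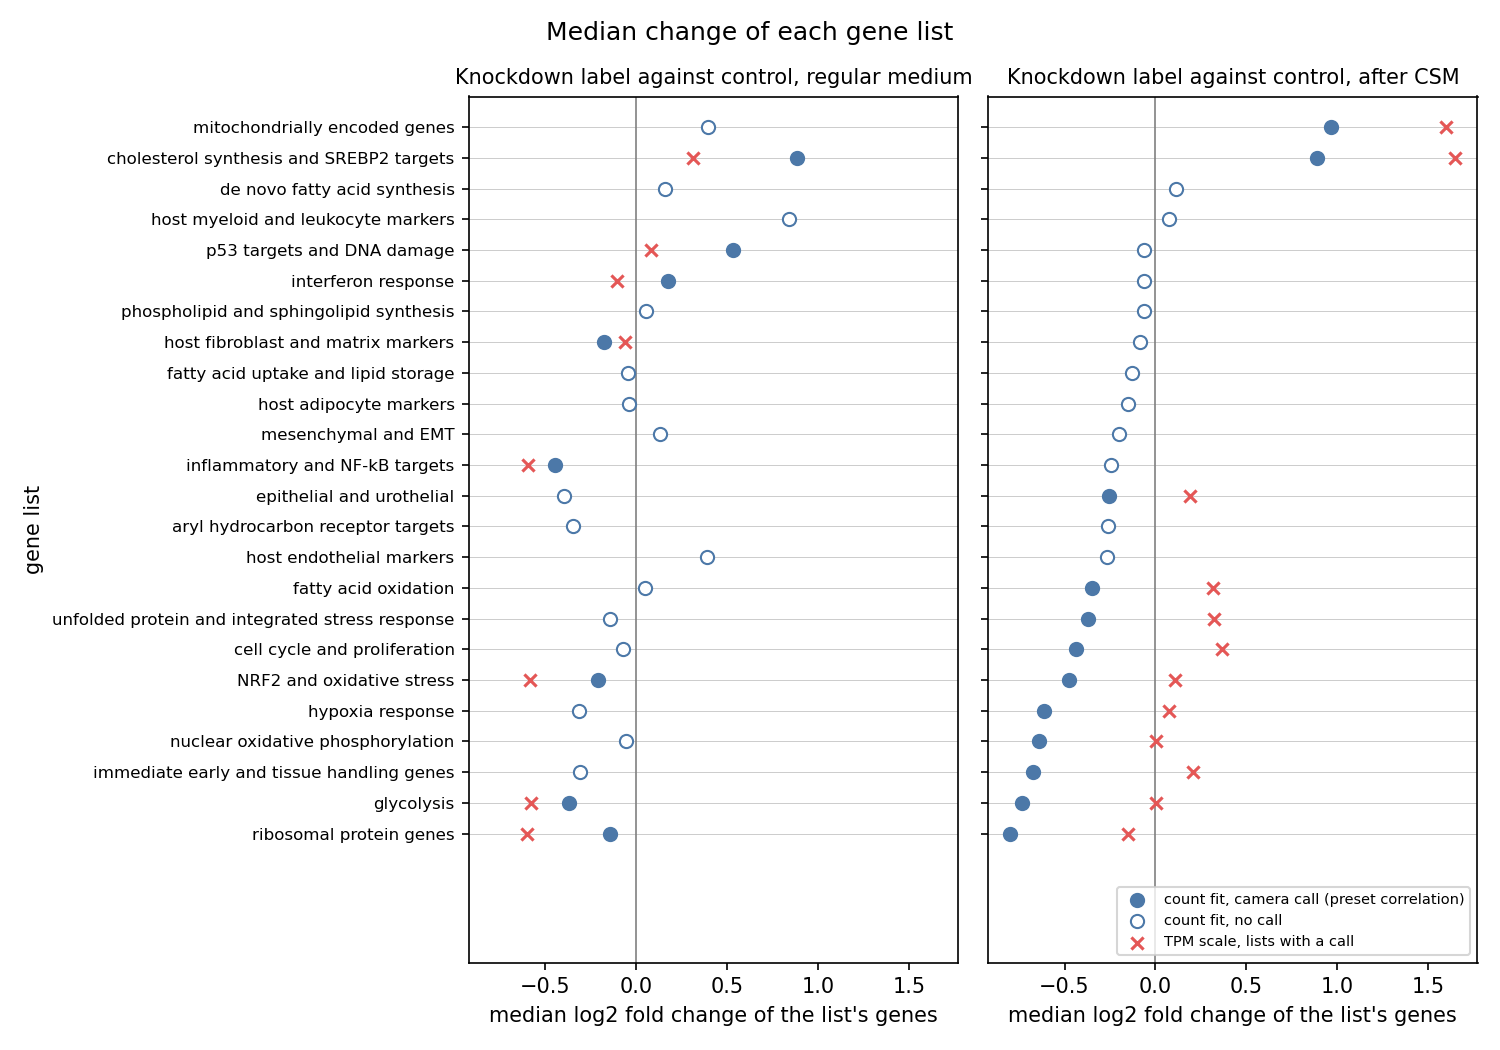
Median log2 fold change of each of 24 gene lists for the knockdown label against control, in regular medium on the left and after CSM on the right, where filled points are lists called by camera with a preset correlation, open points are lists without a call and crosses give the called lists on the TPM scale. Cholesterol synthesis lies at 0.88 and 0.89. In regular medium the interferon median of 0.18 is -0.10 on TPM; after CSM 9 lists with negative medians have TPM medians of 0.00 to 0.37, where the median of all genes moved by 0.39.

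Most genes called for knockdown in regular medium were also called after CSM, in the same direction. Of the 46 and 264 called genes, 34 were called in both media, all with the same sign. These were 3 higher, against 0.0258 for independent lists, and 31 lower, against 0.296. AJAP1, TRPC4, LPAR1, TCF21 and the SPANX copies were among those lower, and COL4A6 and CSMD2 among those higher. All 46 genes called in regular medium had the same sign after CSM. The contrasts share no library. Across the 14098 genes at 2 CPM or more, the log2 fold changes in the 2 media correlated with r = 0.54, across genes that are not independent replicates. Replicate 4 of the libraries labelled FASN knockdown after CSM, at 111% of control for FASN, held AJAP1 at 0.224 CPM and TRPC4 at 0 CPM. COL4A6, higher in both media, was at 14.98 CPM in that library, within the range of the controls after CSM (6.53 to 17.4 CPM), and at 46.7, 58.5 and 37.5 CPM in replicates 1 to 3.

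**Figure D3:**
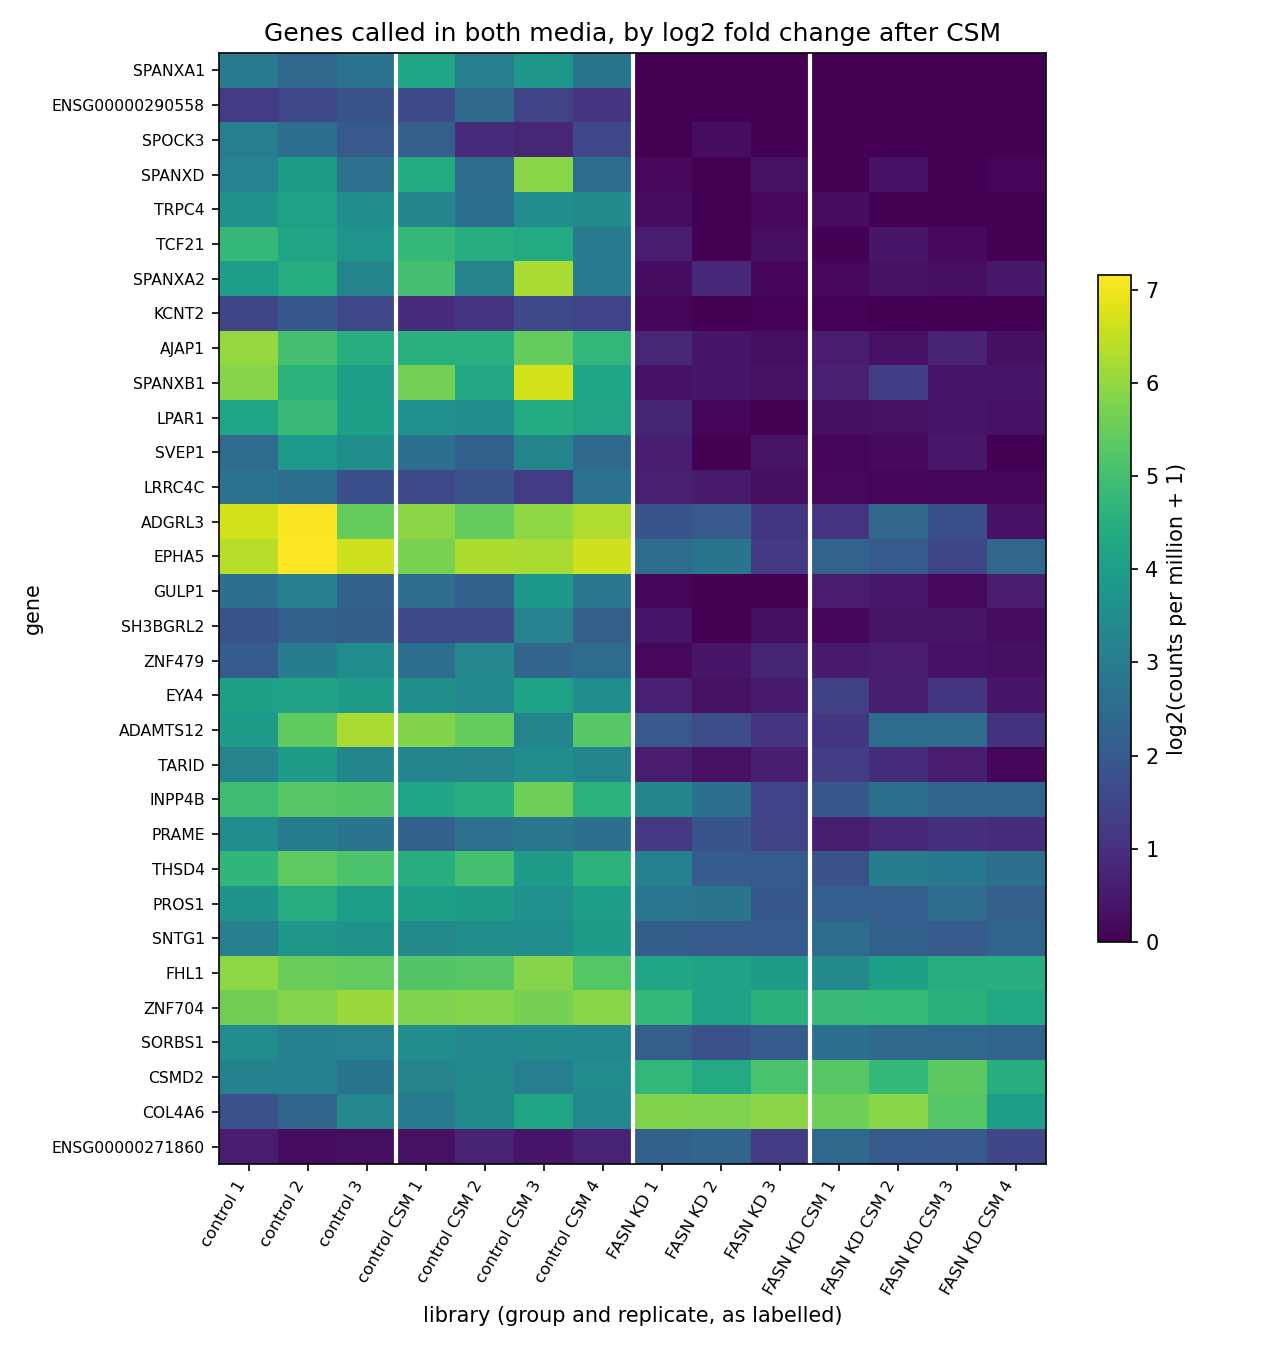
Heat map of log2(CPM + 1) for 32 of the 34 genes called in both media (one line per gene, ordered by log2 fold change after CSM) across the 14 libraries, with white lines between groups. The 29 genes shown as lower are darker in all 7 libraries labelled FASN knockdown, replicate 4 after CSM included, and the 3 called higher are at the bottom.

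CSM before engraftment, compared with regular medium in control cells, left no gene past the test. Interferon genes stood lower and genes of the cell cycle, ribosome and respiration stood slightly higher as groups. In each of these lists single libraries of the media overlapped. The mean log2 CPM of interferon genes was 6.06, 6.81 and 5.39 in regular medium and 5.50, 5.40, 5.75 and 5.71 after CSM. With an estimated correlation none of the list calls that follow was kept: fatty acid oxidation had adjusted p = 0.468 and the other 7 lists had adjusted p = 0.672. Interferon genes fell with 30 of 33 negative (median -0.53, adjusted p = 8.59e-08 in camera with a preset correlation), with RSAD2, an antiviral enzyme, at -1.69 (SE 0.73) and STAT2 at -0.53 (SE 0.26). All 34 cell cycle genes were positive and the list rose (median 0.33, adjusted p = 1.22e-11), with CCNB2 at 0.67 (SE 0.23) and PLK1 at 0.68 (SE 0.25). Oxidative phosphorylation genes rose (median 0.32, adjusted p = 4.98e-11), as did ribosomal protein genes (median 0.29, adjusted p = 1.71e-08) and cholesterol synthesis genes (median 0.33, adjusted p = 8.94e-05). So did p53 targets (median 0.30, adjusted p = 0.000701), fatty acid oxidation genes (median 0.25, adjusted p = 0.00250) and de novo fatty acid synthesis genes (median 0.20, adjusted p = 0.0255). No member of any list was called, adjusted over the list alone or over all genes. edgeR's quasi-likelihood test called 0 of 22560 genes, with 316 at an unadjusted p below 0.05, where DESeq2 called 6. FASN had a log2 fold change of -0.07 (SE 0.30, edgeR adjusted p = 1.00). The aryl hydrocarbon receptor list, meant to catch a response to smoke components, was not called (median -0.10, 4 of 8 positive, adjusted p = 0.886). Its targets CYP1A1, CYP1B1 and ALDH3A1 were not among the 8 tested members, which include AHR and ARNT themselves. A response of those targets was therefore not tested. The NRF2 list was not called either (median -0.03, 13 of 29 positive, adjusted p = 0.962). The interferon call ended without control replicate 2 (median -0.06, adjusted p = 0.395). Calls ended without control replicate 3 of the CSM group for cholesterol synthesis, fatty acid oxidation and de novo fatty acid synthesis (adjusted p = 0.164, 0.0730 and 0.607). They also ended without control replicate 3 of regular medium for de novo fatty acid synthesis, and without control replicate 1 of the CSM group for p53 targets (adjusted p = 0.36).

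In the knockdown cells interferon genes stood lower as a group after CSM, in a comparison that rests on the libraries labelled FASN knockdown after CSM. The 7SL share also differed, with means of 14.1% in regular medium and 4.83% after CSM. Interferon, ribosomal, oxidative phosphorylation, mitochondrially encoded and cell cycle genes differed between knockdown libraries of high and low 7SL across the media. That split was picked from the data, as the one with the most called genes. The mean log2 CPM of interferon genes was 6.60, 6.85 and 5.52 in regular medium and 5.00, 6.16, 6.35 and 4.24 after CSM, so the groups overlap. Of 33 interferon genes 32 were negative and the list fell (median -0.73, adjusted p = 1.0e-12, adjusted p = 0.588 with an estimated correlation), with the antigen presentation genes B2M at -1.14 (SE 0.39) and HLA-C at -0.95 (SE 0.35), and a median of 0.09 on the TPM scale, where all genes moved by 0.59. The cholesterol synthesis list rose (median 0.51, adjusted p = 2.32e-06, adjusted p = 0.588 with an estimated correlation), with HSD17B7 at 1.20 (SE 0.27) and MVK at 0.93 (SE 0.27) and 2 members higher when adjusted over the list alone. De novo fatty acid synthesis rose (median 0.28, adjusted p = 0.00230, adjusted p = 0.588 with an estimated correlation), with FASN called when adjusted over the list alone. FASN had a log2 fold change of 1.31 (SE 0.31) and did not pass over all genes (edgeR adjusted p = 0.568, exact permutation p = 0.0571, where 0.0286 is the smallest possible). Fatty acid oxidation fell (median -0.22, adjusted p = 0.00194, adjusted p = 0.425 with an estimated correlation), with CPT1A at -0.80 (SE 0.19), and its TPM median was 0.61. Another 9 lists were called, with ribosomal protein genes falling (median -0.33, TPM median 0.66, adjusted p = 2.23e-06) and mitochondrially encoded genes rising (median 0.39, adjusted p = 0.00194), both at adjusted p = 0.588 with an estimated correlation. The other 7 were p53 targets (median -0.26, adjusted p = 0.00194), oxidative phosphorylation (median -0.26, adjusted p = 0.000269), hypoxia (median -0.30, adjusted p = 0.0272), NRF2 (median -0.15, adjusted p = 0.0349), stress response (median -0.25, adjusted p = 0.0349), mesenchymal (median -0.22, adjusted p = 0.0471) and immediate early genes (median -0.25, adjusted p = 0.0480), at adjusted p = 0.588 or 0.625 with an estimated correlation. On the TPM scale 6 of the 13 lists kept their direction relative to the shift of all genes. No gene was called by edgeR's quasi-likelihood test, with 1504 at an unadjusted p below 0.05, where DESeq2 called 52. Without replicate 3 of the knockdown in regular medium the calls of cholesterol synthesis and de novo fatty acid synthesis ended (both at adjusted p = 0.592), and without replicate 2 those of fatty acid oxidation, ribosomal protein genes and mitochondrially encoded genes ended (adjusted p = 0.117, 0.951 and 0.838). The p53 call ended without knockdown replicate 3 (adjusted p = 0.592), and that of ribosomal protein genes also without replicate 1 after CSM. Of the rest, oxidative phosphorylation ended without replicate 2 of regular medium (0.891) and replicate 1 after CSM. The NRF2 and stress response calls ended without replicates 1 and 2 of either medium (up to 0.377 and 0.420), and the immediate early call without replicates 1 and 3 of regular medium and 1 and 2 after CSM (up to 0.983). The hypoxia and mesenchymal calls ended without replicate 1 of regular medium (0.882 and 0.858) and replicate 2 after CSM, with replicate 4 after CSM for hypoxia and replicate 1 after CSM for mesenchymal genes.

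The interaction compares the knockdown effect after CSM with that in regular medium. It cannot decide here whether smoke exposure changes what FASN loss does, because the loss itself was unequal. FASN stood at 26.0% of control in regular medium and at 67.6% after CSM. The mean 7SL share of the knockdown libraries also differed, at 14.1% and 4.83%. The knockdown effect on FASN itself differed by 1.38 on the log2 scale (SE 0.42, 95% interval 0.48 to 2.28) and did not pass over all genes (edgeR adjusted p = 0.942). Mean log2 CPM of oxidative phosphorylation genes was 6.02, 6.42 and 5.18 with knockdown in regular medium, and 5.29, 5.72, 5.75 and 5.89 after CSM. For ribosomal protein genes it was 8.89, 9.42 and 8.10, and 7.95, 8.53, 8.67 and 8.92, so the knockdown libraries overlap for both. As lists, the knockdown effect on respiration and ribosome genes was lower after CSM than in regular medium. This difference had a median of -0.63 for oxidative phosphorylation (46 of 48 negative, TPM median 0.43, adjusted p = 6.34e-11 in camera with a preset correlation). For ribosomal protein genes it was -0.58 (58 of 60 negative, TPM median 0.38, adjusted p = 1.21e-11), both at adjusted p = 0.669 with an estimated correlation. With CSM both lists rose in control cells and fell in knockdown cells. A fall or rise of a list in this comparison is one of the difference, not of its level. Fatty acid oxidation fell (median -0.47, TPM median 0.47, adjusted p = 3.59e-05, adjusted p = 0.107 with an estimated correlation), while cholesterol synthesis was not called (median 0.09, adjusted p = 0.188). The p53 list (median -0.67, adjusted p = 1.94e-05), cell cycle (median -0.43, adjusted p = 1.23e-05), mesenchymal (median -0.38, adjusted p = 0.0201) and interferon genes (median -0.18, adjusted p = 0.0255) also fell and mitochondrially encoded genes rose (median 0.46, adjusted p = 0.0251), at adjusted p of 0.669 to 0.738 with an estimated correlation. With 7SL as a covariate, a fit chosen after seeing the data, mitochondrially encoded genes turned to -0.17 and interferon genes to 0.31. On TPM the cell cycle (0.72) and mesenchymal (0.58) medians lay above the shift of all genes. The interferon call ended in 7 of 14 fits without 1 library (adjusted p of up to 0.783 without knockdown replicate 4 after CSM). That of mitochondrially encoded genes ended in 5 (0.707 without knockdown replicate 2 of regular medium) and that of mesenchymal genes in 3 (0.337 without knockdown replicate 1 of regular medium). edgeR's quasi-likelihood test called 0 genes, with 1178 at an unadjusted p below 0.05, and DESeq2 called 7. On the TPM scale the median of all genes moved by 0.57, and 5 of the 7 falling lists lay below that shift, oxidative phosphorylation by 0.14, ribosomal protein genes by 0.19, fatty acid oxidation by 0.10, p53 targets by 0.35 and interferon genes by 0.01. The CSM effect in control cells and the knockdown effect after CSM correlated across 14098 genes with r = -0.37, where unchanged simulated groups that share the same control libraries gave a mean of -0.46 (-0.50 to -0.43). The covariance of -0.0720 differs from the simulated -0.0721 by 0.000162, and with the shared libraries divided into 6 pairs of separate sets r ranged from -0.16 to 0.23. The CSM effects in control and knockdown cells correlated with r = -0.13.

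The main axis of variation among the libraries followed the 7SL share. The first principal component, 35.3% of the variance of log2 CPM, followed the log2 share of 7SL with r = 0.828 over 14 libraries (permutation p = 0.00032) and rho = 0.824 (permutation p = 0.00052), with r = 0.768 without the 2 libraries farthest from the median share and r = 0.918 within groups. Of the 24 list levels set against 7SL, mitochondrially encoded genes followed it inversely, with r = -0.870 (permutation p = 5e-05, adjusted p = 0.00120) and rho = -0.837 (permutation p = 0.00033, adjusted p = 0.00792), r = -0.748 without the 2 farthest libraries and r = -0.890 within groups. Interferon genes had r = 0.631 (permutation p = 0.0151, adjusted p = 0.123) and rho = 0.556 (permutation p = 0.0421, adjusted p = 0.325), with r = 0.604 without the 2 farthest libraries and r = 0.525 within groups, which did not pass the adjustment. Cholesterol synthesis genes had r = 0.0380 (permutation p = 0.899, adjusted p = 0.937) and rho = -0.0154 (permutation p = 0.964, adjusted p = 0.964), with r = -0.267 without the 2 farthest libraries and r = 0.594 within groups.

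**Figure D4:**
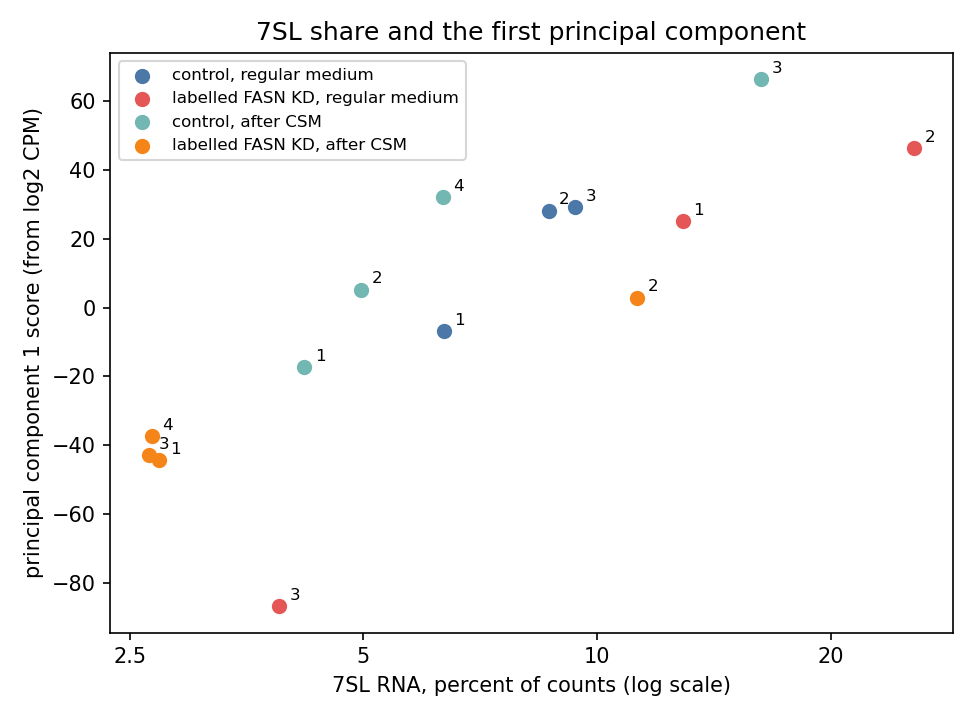
Share of 7SL RNA in percent of counts (log axis) against the score on the first principal component for the 14 libraries, coloured by group and numbered by replicate. Libraries with more 7SL have higher scores (r = 0.828), from -86.8 in replicate 3 of the FASN knockdown to 66.3 in replicate 3 of the control after CSM.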

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

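The tests of the first 2 patterns below, FASN in replicate 4 and the genes called lower with knockdown, were chosen only after the results were seen, and so were the fits with 7SL as a covariate. Of 109 groups of 4 libraries examined for a library far from the other 3, 9 had one, where chance gives about 5% of groups, or 5.45. Among the libraries labelled FASN knockdown after CSM these were the total counts of replicate 4 at 42612442 (others 28478738 to 30320484), the 7SL share of replicate 2 at 11.3% (others 2.64% to 2.73%), and the mean log2 CPM of p53 targets in replicate 1 at 5.97 (others 4.65 to 4.68), of glycolysis genes in replicate 3 at 7.65 (others 6.85 to 6.98) and of endothelial markers in replicate 2 at 0.81 (others 0.66 to 0.69). Among the control libraries after CSM they were the hypoxia genes of replicate 1 at 7.09 (others 5.93 to 6.09), AJAP1 in replicate 3 at 43.2 CPM (others 22.3 to 25.8), PPARGC1A in replicate 1 at 46.4 CPM (others 2.21 to 8.42) and DSP in replicate 4 at 6.02 CPM (others 0.454 to 1.38).

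The knockdown effect differed between the media in a test of the difference itself for FASN, by 1.38 on the log2 scale before adjustment (edgeR p = 0.00525, adjusted p = 0.942 over all genes), and for 8 lists in camera with a preset correlation. Their interaction medians were -0.47 for fatty acid oxidation, -0.67 for p53 targets, -0.63 for oxidative phosphorylation, 0.46 for mitochondrially encoded genes, -0.43 for the cell cycle, -0.38 for mesenchymal genes, -0.18 for interferon genes and -0.58 for ribosomal protein genes. None of the 8 was called with an estimated correlation.

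FASN at the control level in replicate 4 of the libraries labelled FASN knockdown after CSM could reflect a wrong label or a mixed sample, but over 39 other genes called lower in regular medium, the median level in that library was 4.69% of the controls after CSM (7.80%, 7.91% and 7.91% in replicates 1 to 3), which argues against control cells as the source of its FASN. Of the 6 genes called higher, 4 lay above all controls after CSM in that library, while COL4A6 at 14.98 CPM and PRICKLE1 at 108 CPM lay within them (0, 0 and 1 of the 6 did in replicates 1 to 3). The 57 host markers under 1 CPM in control libraries summed to -4.30 CPM relative to knockdown libraries from regular medium, against a FASN excess of 361 CPM. Mouse transcripts were not quantified, so these human markers need not rise with mouse cells, and this cannot decide on mouse cells as the source. Replicates 1 and 3 had the same 7SL share, and FASN in replicate 4 lay 178 CPM above the higher of them, against an SD of at most 104 CPM in the other groups, which argues against 7SL. Regained FASN expression in knockdown cells may explain it, which was not tested.

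The 39 other genes called lower in regular medium, many of them nearly absent with knockdown in both media, have several possible sources. They could follow the FASN RNA level, a lasting effect of low FASN, or a difference between separately derived populations. If they followed the FASN RNA of the same library, their levels would rise with it, but the highest of the 4 library medians after CSM was 7.91% of control, where the lowest FASN level was 38.5%. Below 25% of control stood 30, 28, 26 and 27 of these genes in replicates 1 to 4. The highest single genes stood at 130%, 70.8%, 90.2% and 81.2%, so the medians do not speak for each gene. Of the 39 genes, 36 did not overlap between groups after CSM (chance 1.43% per gene), which separate derivation and a lasting knockdown effect would both give, so these cannot be told apart. With 1 SPANX copy kept and genes without a position left out, 35 of these genes remained. Among them 9 pairs lie within 5 Mb, against a mean of 3.04 pairs in 10000 random sets (0.97% had as many). Some pairs share a gene and are not independent, as EYA4, TCF21 and TARID pair with each other. The other 17 genes between such neighbours had a median log2 fold change of -0.16, but they cover 2 of the 6 chromosomes with pairs, so loss of segments stays open.

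The 7 knockdown libraries form 2 sets that cross the media, found among the other splits of the samples: replicates 1 and 2 from regular medium with replicate 2 after CSM (7SL 12.9%, 25.6% and 11.3%), and replicate 3 from regular medium with replicates 1, 3 and 4 after CSM (3.89%, 2.73%, 2.64% and 2.67%). Between them edgeR called 1007 genes, 763 higher and 244 lower in the first. Among the 7 control libraries, 94.6% of these genes moved the same way with 7SL, against 77.8% of other genes, so a shared technical or tissue state marked by 7SL may underlie the sets. Swapped medium labels would make the sets the media, and 38.2% moved the same way as CSM in control cells. That bound assumed a CSM effect in control cells, where edgeR called 0 genes (316 at an unadjusted p below 0.05, 6 by DESeq2), so a swap stays open.

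Other splits of the same samples were counted for each comparison. For knockdown in regular medium the real split called 46 genes and the highest other split 0, while 3 of the 9 other splits had more genes at an unadjusted p below 0.05 (up to 3343, against 2049). The 10 splits, of which 1 was as large, are too few for a share under 0.05. After CSM, 1 of 35 splits was as large, the real one with 264 genes, and the highest other called 1, which argues against a grouping by chance. For CSM in control cells, CSM in knockdown cells and the interaction edgeR called 0 genes, so each split calls at least as many by necessity (35 of 35, 35 of 35 and 100 of 100), and these counts test nothing. The highest other split called 1, 1007 and 1199 genes. Splits with 1007 and 1199 genes point to a structure of the samples other than their labels.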

How the results depend on the processing

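The fits with 7SL as a covariate and without the 2 libraries over 15% 7SL were chosen after seeing the data. Where a value moved the cause was not tested. For the 38 called results of named genes other than FASN, 769 alternatives gave the same direction and side of the threshold in 582 and a lost call in 187, with 0 reversed. In total 11 results kept both in every alternative run: AJAP1, SPANXA1 and TRPC4 in both media, GULP1 and SPANXB1 in regular medium, and SPANXA2, SPANXD and TCF21 after CSM. For the 49 called lists, 1130 alternatives gave 865 the same, 250 with a lost call and 15 reversed. Genes called for knockdown in regular medium, 46, numbered 346 with DESeq2, 389 with no filter on low counts, 25 from only the groups of the contrast, 23 with a length offset, 17 on TPM, 134 with the 7SL covariate, and 18 without the 2 libraries over 15% 7SL. They numbered 11 to 61 without 1 library (29, 11 and 18 without control replicates 1, 2 and 3, and 17 and 27 without knockdown replicates 2 and 3). After CSM the 264 became 1452 with DESeq2, 1178 with no filter, 127 with a length offset, 59 on TPM, 492 with the host score as covariate, and 134 without the 2 libraries over 15% 7SL. There were 86 to 174 without 1 library (174, 89, 118 and 108 without control replicates 1 to 4, and 86, 141, 95 and 142 without replicates 1 to 4 of the libraries labelled FASN knockdown after CSM). Where edgeR called 0 genes, DESeq2 and the fit with no filter called 6 and 62 for CSM in control cells, 52 and 175 in knockdown cells and 7 and 121 for the interaction. The 7SL covariate gave 1 and 3 for the first 2, and each fit without 1 library gave 0 (0 to 0).

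The call of FASN in regular medium was lost from only the groups of the contrast (-1.95, adjusted p = 0.0625), with a length offset (-1.66, adjusted p = 0.0562), on TPM (-1.88, adjusted p = 0.762), with the host score (-1.89, adjusted p = 0.0504), without the 2 libraries over 15% 7SL (-1.83, adjusted p = 0.126) and in every fit without 1 library (-2.06 to -1.72). FASN after CSM was -0.90 to -0.37 without 1 library and reversed to 0.19 on TPM (adjusted p = 0.802), and for CSM in control cells it was -0.18 to 0.15. Over all alternatives FASN ranged from 0.90 to 1.91 for CSM in knockdown cells and from 1.01 to 2.07 for the interaction. In 15 of the alternatives a called list reversed its direction in camera, which weighs a list against all other genes. On the TPM scale, medians of called lists changed sign more often. They did so in 1 of 8 lists for knockdown in regular medium and in 9 of 12 after CSM. For CSM it was 0 of 8 in control cells and 10 of 13 in knockdown cells, and for the interaction 7 of 8. The reversals in camera were as follows. Ribosomal protein genes in regular medium ranged from -0.49 to 0.050 without 1 library, the latter without knockdown replicate 3. For CSM in knockdown cells, the reversed lists were NRF2 (0.81), oxidative phosphorylation (0.72) and stress response genes (0.64) on TPM. With the 7SL covariate they were oxidative phosphorylation (0.18), mitochondrially encoded (-0.35) and ribosomal protein genes (0.021). Oxidative phosphorylation was 0.016 without the 2 libraries over 15% 7SL and -0.44 to 0.016 without 1 library, the latter without knockdown replicate 2. Hypoxia genes were -0.50 to 0.078 without 1 library (the latter without knockdown replicate 1) and immediate early genes -0.42 to 0.25 (without knockdown replicate 3). For the interaction they were mitochondrially encoded genes with the 7SL covariate (-0.17) and without the 2 libraries (-0.10), cell cycle genes on TPM (0.72) and interferon genes with the 7SL covariate (0.31). Ribosomal protein and oxidative phosphorylation genes after CSM kept their calls with the 7SL covariate (-0.63 and -0.45) and without the 2 libraries (-0.69 and -0.52).

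A block by replicate number gave 17 and 59 called genes for knockdown in regular medium and after CSM, and FASN at -1.94 (adjusted p = 0.0847). The numbers do not pair the samples: 0 of 14 libraries correlated best with a library of their own number, and the correlations over 13 pairs ran from -0.39 to 0.45. The least deep library, replicate 2 of the FASN knockdown, held 15810287 counts. What depth limits was not tested apart from leaving it out, which gave 17 called genes.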

Other observations

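The genes described in this part were chosen after their values were seen. Among the 31 genes called lower in both media are several with known roles in signalling and in tumours. The ephrin receptor gene EPHA5 fell by 4.78 in regular medium and by 4.55 on the log2 scale after CSM, and the adhesion receptor gene ADGRL3 fell by 5.41 and 4.96. The phosphoinositide phosphatase gene INPP4B fell by 2.76 and 2.79, the tumour antigen gene PRAME by 2.03 and 2.69 and the protein S gene PROS1 by 1.72 and 1.89. The directions after CSM rest on the libraries labelled FASN knockdown after CSM, in which replicate 4 held FASN at 111% of control.

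Some lipid and xenobiotic genes went the same way in both media without passing the test over all genes. SPTLC3, of sphingoid base synthesis, had log2 fold changes of 2.11 and 1.55 (edgeR adjusted p = 0.0748 and 0.0585), the receptor gene AHR had -1.71 and -1.57 (edgeR adjusted p = 0.233 and 0.0735), and SLC7A11 had -1.99 and -1.44 (edgeR adjusted p = 0.0920 and 0.0711).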
